A study of Homo sapiens with 6 samples.

How the data were processed

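Total RNA of PC3 and LNCaP prostate cancer cells, with and without overexpressed Myc-tagged PURα, was amplified from an oligo(dT) primer, labelled with biotin and hybridised to Affymetrix U133 Plus 2.0 arrays by the authors. The table deposited by the authors holds 1 linear intensity value (MAS5 signal) per probe set and array, made with GCOS 1.4 and MAS5 per the submitters' processing notes. Each of the 6 columns has a 2% trimmed mean of about 150 (150.018, and 150.017 on one array) and the columns do not share their quantiles. The series' design text describes RMA with quantile normalization and an empirical Bayes Gamma-Gamma model for the authors' own results, and these columns hold neither those values nor their calls. No detection calls were used. The highest signals were between 21789.2 and 30384, and the arrays correlated at r = 0.970 (LNCaP vector 1 and 2), 0.966 (LNCaP PURα 1 and 2), 0.957 (PC3) and between 0.854 and 0.865 across lines.

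The samples form 4 groups: PC3 mock (1 array, mixed population with empty plasmid), PC3 PURα (1 array, a clone), LNCaP vector (2 arrays) and LNCaP PURα (2 arrays). PC3 was grown in DMEM and LNCaP in RPMI-1640, so medium and line go together. Probe sets were named with the platform's annotation table, with gene IDs looked up in a RefSeq gene table for GRCh38.p14, which changed 0 symbols. Of the 54675 probe sets, 62 controls were left out, 41091 read 1 gene, 1801 several and 11721 none; the last 2 kinds were tested and counted but not named. This gave 19775 genes.

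Arrays were scaled to the same median and values transformed to log2(signal + 16). Signals printed for single arrays are those deposited; log2 changes and folds are on the log2(signal + 16) scale after scaling, which understates the change of dim genes. Probe sets whose mean log2 value over the arrays in a fit lay above the 50th percentile were tested, 27306 in each fit. Tests were run in R 4.3.3 with limma 3.58.1 (linear model, moderated variance with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The fits were LNCaP PURα against vector on the 4 LNCaP arrays, PURα against control over all 6 arrays with cell line as a term, and PC3 against LNCaP with PURα as a term. The difference of the PURα effect between lines was fitted on the 4 groups, where the spread comes from LNCaP and PC3 arrays are assumed to vary like them. PC3 PURα against mock has 1 array per arm, so log2 differences and the number of probe sets differing 2-fold or more are given with no test, beside the same counts between arrays of 1 LNCaP group.

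Gene lists covered 18 groups: ER chaperones, folding and ER-associated degradation, the ATF4 and CHOP stress response, heat shock proteins, androgen response, and luminal, basal, neuroendocrine and mesenchymal markers. The others were DNA replication, mitosis, p53 targets and cyclin-dependent kinase inhibitors, interferon, NF-kB, cholesterol and fatty acid synthesis, hypoxia and glycolysis, Notch, BMP, TGF-beta and Wnt targets, ribosomal proteins, and blood, endothelial and fibroblast markers. They were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, on the brightest probe set per gene, adjusted over the 18 lists. Some genes stand in several lists (DDIT4 and NDRG1 in the hypoxia list and in the ATF4 or androgen list). In PC3 a list's median was placed among 10000 random lists of the same size drawn within 20 expression bins. The lists, tests and alternatives other than those named as added later were fixed before the data were examined. So was the rule for named genes. It reads each gene by its brightest probe set, so a gene that passed on another probe set alone is counted but not named. It takes all PUR family probe sets, and in LNCaP and over both lines the 12 genes with the largest rise and the 12 with the largest fall among those passing, filled up with the strongest below the threshold where fewer passed. In PC3 it takes the 12 largest differences each way, in each list the 4 members with the largest change, and between lines the 6 largest each way and the androgen list. Other probe sets of a named gene are given where they go the other way. Among list members, 27 of 69 named in LNCaP, 20 of 68 over both lines and 8 of 68 in PC3 had such a probe set, mostly a dim one, and these are given for the members printed.

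Alternatives were no filter, a filter at the 70th percentile, quantile normalisation, pseudocounts of 1 and 64, no intensity trend, and robust moderation. Further ones were 1 probe set per gene, the mean over a gene's probe sets for lists, an estimated correlation, a threshold of 0.1, a Gamma-Gamma model at a posterior above 0.5, and leaving out each array in turn. The authors' scaling kept as deposited was added after the data were seen, as were fits with the prior degrees of freedom held infinite, list medians per pair of arrays and camera on the difference between lines and on the lines themselves. The methods were tested on simulated data with 200 changed probe sets, counting those among the 27306 that passed the filter in each fit. The simulated noise was independent between probe sets, with a single SD for probe sets of like intensity. It lacks variances particular to a probe set and correlation between genes, so the results below may be better than on the real arrays. The LNCaP fit recovered 57.3% of 89 changes of 1 log2 unit and 100% of 84 changes of 2 with 11 false calls. The fit over both lines recovered 73.3% of 86 and 100% of 82 with 9, and the fit of the difference between lines 0% of 92 and 48.9% of 94 with 4. A simulated list shift on 12630 genes of the LNCaP comparison gave p = 7.0e-17 by camera with the preset correlation, under which 1 other fixed list was also called, and p = 0.192 by camera with an estimated one. With an estimated correlation, not passing therefore does not show that a list did not shift. The Gamma-Gamma model recovered 36.0% and 100% of the LNCaP changes and called 86 unchanged probe sets.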

Results

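Total RNA from 2 human prostate cancer cell lines was measured on 6 whole-genome expression arrays, to ask which genes change when PURα is overexpressed. PURα, the product of PURA, binds purine-rich single-stranded DNA and RNA. PC3, an androgen-independent line from a bone metastasis, gave 1 array of a mixed population carrying the empty plasmid (mock) and 1 array of a single clone carrying Myc-tagged PURα. LNCaP, an androgen-responsive line from a lymph node metastasis, was infected with a retrovirus carrying PURα or with the empty virus (vector), selected with puromycin for 72 h, and gave 2 arrays per arm from independent infections. Each array held 54675 probe sets. The median signal was 38.9 (PC3 mock), 38.2 (PC3 PURα), 36.5 and 39 (LNCaP vector 1 and 2), 41.7 and 34.6 (LNCaP PURα 1 and 2). Scaling to the same median moved single arrays by between −0.13 and 0.14 on the log2 scale. The ratio of the 3′ to the 5′ actin probe set, a sign of RNA integrity, was 1.94 on LNCaP PURα array 1, between 1.53 and 1.55 on the other LNCaP arrays, and 1.29 and 1.30 on the PC3 arrays. With 1 or 2 arrays per arm, the number of arrays limits the precision of every value below.

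The first question was whether the cells express the introduced gene. PURA itself was higher in all 3 PURα arrays, than in the controls of the same line, on 3 of its 5 probe sets (called A to E here): B, C and the dim E. On probe set B the LNCaP signal rose from 658 ± 4.81 to 2302 ± 293 (SD, n = 2 each), a log2 change of 1.77 (SE 0.23, adjusted p = 4.8e-10). The PC3 signal was 281.4 in mock and 1881 in PURα cells (6.49-fold). Probe set C rose from 7.1 to 210.1 in LNCaP (log2 3.30, SE 0.32, adjusted p = 3.7e-20). It read 3.7 in PC3 mock and 19090.2 in PC3 PURα cells. The other PURA probe sets with signal, A and D, had LNCaP log2 changes of 0.05 and −0.19 and did not pass, and E read little (11.6 and 12.9 in PC3, 16.6 and 23.6 in LNCaP control and PURα cells). The adjusted p of B stayed under 0.05 in 13 of 14 alternatives, from 8.9e-11 to 0.515, the highest without the filter on dim probe sets. In the control cells PURA was lower in PC3 than in LNCaP on B (281.4 against 658) and on A (430.1 against 691), while C was near 0 in both. PURB was read by a single dim probe set (42.5 and 104.9 in PC3 mock and PURα, 12.4 and 3.05 in LNCaP vector and PURα). The brighter PURG probe set read 76.6 and 47.4 in PC3 and 44.0 and 59.8 in LNCaP (log2 0.31, not passing).

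**Figure D1:**
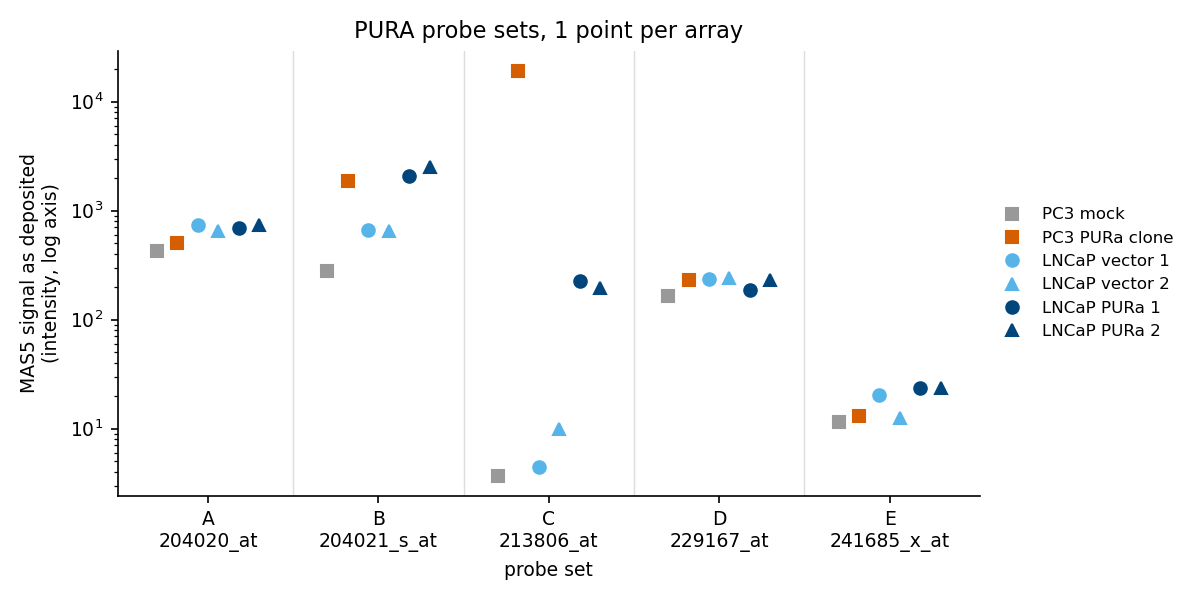
MAS5 signal of the 5 PURA probe sets, A to E, on a log axis, 1 point per array, squares for PC3, circles and triangles for LNCaP arrays 1 and 2. On B the 3 PURα arrays read 1881, 2094.7 and 2509.3, above the 3 control arrays at 281.4, 661.8 and 655.

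LNCaP was compared with its vector control to ask which genes follow PURα in an androgen-responsive line. The gene that rose most besides PURA among bright probe sets was S100P, a calcium-binding protein, from 1164 ± 661 to 3954 ± 1070 (SD, n = 2; log2 1.84, SE 0.23, adjusted p = 2.6e-11). Others that rose were FUT7, a fucosyltransferase that makes sialyl Lewis X (log2 1.62, adjusted p = 0.0114), the carbonyl reductase CBR3 (1.17, 0.0103), and the myosin light chain MYL10 (2.14, 1.8e-06, but −0.05 on another probe set). So did the scaffold protein gene TAMALIN (1.22, 0.0317), MTFR1L (1.20, 0.0206), the pseudogene ELK2AP (1.31, 0.0027) and the antisense transcript GLYATL1-AS1 (1.55, 0.0199). Genes that fell included the histone variant H2AJ, from 80 ± 2.12 to 11.9 ± 4.17 (log2 −1.81, SE 0.38, adjusted p = 0.0027, but 0.14 and 0.07 on dim other probe sets), the zinc finger factor SALL2 (−1.37, 0.0208), NUTM1 (−1.57, 0.0011), MYRF-AS1 (−1.50, 0.0107, but 0.19 on another probe set) and TRIM52-AS1 (−1.11, 0.0350). The adhesion molecule ICAM1 fell on its brightest probe set (log2 −1.72, adjusted p = 1.0e-05), but its 2 other probe sets went the other way (1.17 and 0.22). The cartilage proteoglycan ACAN also fell on its brightest probe set (−1.37, 0.0492) with 0.62, 0.07 and −0.54 on its others. Values just short of the threshold were 1.26 for DNAH1 (between −0.96 and −0.02 on 7 other probe sets), 1.09 for DEFB124 (−0.08 on another) and 0.96 for ENPP4. On the lower side they were −1.22 for LRRC37A4P, −1.35 for HCST, −0.96 for SNHG4, −1.08 for LOC389199 and −0.98 for SYT15 (0.45 on another probe set).

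In limma, 40 of 27306 probe sets passed in LNCaP, 20 higher and 20 lower, reading 18 genes that rose and 13 that fell, of which 9 and 7 passed on their brightest probe set and are named. At the same time 1071 had an unadjusted p under 0.05 where 1365.3 are expected without any change. Of the 40, 33 lay under a mean signal of 100, against 38.5% of the probe sets tested. With quantile normalisation 2 probe sets passed, both higher, and with the authors' scaling again 2, both higher: the PURA probe sets B and C. The count was 15 without vector array 2, 18 without vector array 1, 97 without PURα array 1 and 185 without PURα array 2. Of the 16 named genes that passed, PURA alone passed in all 4 of these fits. Without vector array 1, calls were lost for S100P (1.28), ELK2AP (0.86), CBR3 (1.48), FUT7 (1.45), GLYATL1-AS1 (1.55), NUTM1 (−1.42), MYRF-AS1 (−1.81), SALL2 (−1.56), TRIM52-AS1 (−1.10) and ACAN (−1.27), and TAMALIN moved to 1.83. Without vector array 2 they were lost for CBR3 (0.86), FUT7 (1.78), GLYATL1-AS1 (1.56), MTFR1L (0.76), TAMALIN (0.61), ICAM1 (−1.68), NUTM1 (−1.72), SALL2 (−1.19), TRIM52-AS1 (−1.12) and ACAN (−1.46). Without PURα array 1 they were lost for ELK2AP (1.12), TAMALIN (1.17), ICAM1 (−0.87), SALL2 (−1.24), TRIM52-AS1 (−0.27) and ACAN (−0.77), and MYL10, at 43.4 and 287.1 on the PURα arrays, moved to 3.43. Without PURα array 2 they were lost for CBR3 (1.09), MTFR1L (1.02), TAMALIN (1.26) and MYRF-AS1 (−1.04), and TRIM52-AS1 moved to −1.94; genes missing here kept their call or fell under the filter.

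The fixed lists ask whether whole pathways, foremost the ER stress response and differentiation, follow PURα. As groups, genes of the unfolded protein response and of the linked ATF4 stress response had small median changes above 0 in LNCaP cells. The lists passed only with the preset correlation of 0.01, which takes members as nearly independent. The estimated correlation was 0.58 for the ER list and 0.93 for the ATF4 list. The list of ER chaperones, folding and ER-associated degradation had a median log2 change of 0.15 over 29 members, 25 of them above 0 (camera adjusted p = 1.9e-04, and adjusted p = 0.853 with an estimated correlation). HERPUD1, which works in ER-associated degradation, rose when adjusted over the list alone, from 1996 ± 346 to 3504 ± 102 (SD, n = 2; log2 0.81, SE 0.23), with −0.13 on a dim other probe set. The chaperone HSPA5 (BiP) had 0.47, DNAJC3 0.38 and the sensor ATF6 0.38, none of which passed, and ATF6 had −0.73 and −1.02 on other probe sets. Of the 29 members, 10 were higher in both PURα arrays than in both vector arrays and 1 was lower, against 3 higher of the 31 in the ATF4 and CHOP list, where chance gives 16.7% each way and all genes gave 12.8% and 11.5%. The ATF4 and CHOP list had a median of 0.23 over 31 members, 30 of them above 0 (adjusted p = 4.6e-09, and adjusted p = 0.853 with an estimated correlation). Adjusted over the list alone, 2 of its members rose, the stress factor NUPR1 (log2 0.77) and DDIT4, an inhibitor of mTORC1 (0.68). DDIT3, which encodes CHOP, had 0.56 and CEBPB 0.51 without passing. Comparing each PURα array with each vector array, the ER list read −0.02 and 0.01 for PURα array 1 and 0.29 and 0.30 for PURα array 2. Median scaling had moved these 2 arrays by −0.13 and 0.14. With quantile normalisation the arrays read alike on the list, at 0.21 and 0.10 each. With the authors' scaling they read 0.17 and 0.11 (array 1) and 0.22 and 0.13 (array 2). The ATF4 list read −0.24, 0.13, 0.37 and 0.72. Arrays of the same group differed by −0.02 and 0.33 on the ER list and by 0.33 and 0.61 on the ATF4 list. Over the alternatives the adjusted p ran from 8.3e-08 to 0.853 for the ER list and from 9.1e-21 to 0.853 for the ATF4 list.

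Androgen response genes also had a higher median in LNCaP (0.18 over 24 members, 19 above 0, adjusted p = 0.0270), with 0.60 for KLK3, which encodes prostate-specific antigen, 0.44 for TRPM8 (−0.23 on another probe set), 0.35 for KLK2 and 0.33 for STEAP2. Lower medians passed for mitosis and G2/M (−0.11 over 40 members, 5 above 0, adjusted p = 0.0119; CENPE −0.35, ASPM −0.31) and for DNA replication and G1/S (−0.11 over 38, 9 above 0, adjusted p = 0.0473; MCM5 −0.39, MCM2 −0.34). Cholesterol and fatty acid synthesis was lower as well (−0.08 over 23, 5 above 0, adjusted p = 0.0396; ELOVL6 −0.54, LSS −0.49, but 0.08 on another probe set). Under median scaling PURα array 1 against vector array 1 gave medians of −0.34 for mitosis, −0.34 for DNA replication and −0.28 for cholesterol synthesis, while PURα array 2 gave 0.11, 0.07 and 0.10 against vector array 2 and −0.10, −0.08 and −0.07 against vector array 1. With quantile normalisation or the authors' scaling every such comparison was below 0 for these 3 lists. No member of these 4 lists passed alone, and each list had an adjusted p = 0.853 with an estimated correlation. That is the highest over the alternatives, with the lowest at 0.0018 (androgen), 3.3e-04 (mitosis), 0.0042 (DNA replication) and 0.0057 (cholesterol). The remaining lists did not pass: luminal and epithelial markers 0.07 (ACP3, prostatic acid phosphatase, 0.64), basal markers 0.06, mesenchymal markers −0.06, p53 targets and kinase inhibitors 0.02, interferon response −0.01 and NF-kB −0.05. The same holds for hypoxia and glycolysis (0.08), Notch, BMP, TGF-beta and Wnt targets (−0.11), ribosomal proteins (0.07), heat shock proteins (0.03) and blood, endothelial and fibroblast markers (0.10). With the authors' scaling ribosomal proteins passed (0.08, camera adjusted p = 0.0067, and adjusted p = 0.715 with an estimated correlation). Neuroendocrine differentiation did not pass either, and its median was 0.08 while its mean was −0.0097 and its test pointed up. In these lists GDF15, a stress-induced cytokine, rose when adjusted over the list alone (log2 0.88), and ICAM1 fell over all genes and over its list alone.

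Single arrays moved these list results under median scaling. Leaving out PURα array 2 turned the ATF4 median to −0.027 and ended its call, as did leaving out vector array 1 (0.062), while it was 0.41 without vector array 2 and 0.54 without PURα array 1. The ER list passed in all 4 such fits, with medians of 0.18 and 0.12 without vector array 1 or 2, 0.29 without PURα array 1 and 0.015 without PURα array 2. The androgen list lost its call without vector array 1 (0.17), vector array 2 (0.12) or PURα array 1 (0.20), and its median was 0.076 without PURα array 2. Mitosis lost it without vector array 1 (−0.0075) or PURα array 1, where the median turned to 0.0072, and read −0.22 without vector array 2 or PURα array 2. DNA replication lost it without vector array 1 (−0.013), PURα array 1 (−0.011) or PURα array 2 (−0.22) and read −0.21 without vector array 2. Cholesterol synthesis lost it without vector array 1 (−0.036), vector array 2 (−0.18) or PURα array 1 (−0.020) and read −0.21 without PURα array 2.

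The arrays of both cell lines were fitted together to ask which genes follow PURα in either background. Those that rose were PURA (log2 2.08, SE 0.20, adjusted p = 9.8e-06), S100P (1.92, SE 0.24, adjusted p = 3.7e-04), and HERPUD1 (0.94, SE 0.17, adjusted p = 0.0377, but −0.16 on a dim probe set). So did MARF1, which encodes an RNA-cleaving regulator of meiosis (1.14, SE 0.21, adjusted p = 0.0401), FAM241B (1.00, SE 0.18, adjusted p = 0.0412) and FUT7 (1.58, adjusted p = 0.0481), while H2AJ fell (−1.51, SE 0.24, adjusted p = 0.0097, but 0.07 in LNCaP and 0.67 in PC3 on a dim probe set). S100P read 39 in PC3 mock and 213.3 in PC3 PURα cells. HERPUD1 was higher in all 3 PURα arrays than in the controls of the same line, at 621.6 and 1428.4 in PC3 mock and PURα cells, 1751.2 and 2240.5 on the LNCaP vector arrays and 3431.3 and 3576.2 on the LNCaP PURα arrays. Short of the threshold were DDIT4 (1.34), RASD1 (1.23), ENPP4 (0.97), NUPR1 (0.83), HSPA13, an ER-associated chaperone (0.81), and MYADM (0.78, and −0.04 on another probe set). On the lower side they were FSD1 (−1.37), MIR1-1HG (−1.22), MYRF-AS1 (−1.22), TRIM52-AS1 (−1.20), TNFRSF11A (−1.11), CA7 (−1.07), CDH11 (−1.03), ZBED3-AS1 (−0.92), RAP1A (−0.84 on its brightest probe set, 0.37 and 0.17 on others), HMGA1 (−0.69) and PTPRO (−0.57). Dim other probe sets had 0.19 and 0.14 in LNCaP and 0.85 and 0.01 in PC3 for PTPRO, and 0.19 and −0.11 for MYRF-AS1. In all, 12 of 27306 probe sets passed, 11 higher and 1 lower. With quantile normalisation or the authors' scaling 1 passed, probe set B of PURA. The count was 0 without LNCaP PURα array 2 (limma, with 2354 at an unadjusted p under 0.05), 1 without LNCaP PURα array 1, 36 without PC3 mock and 43 without PC3 PURα. It was 48 without LNCaP vector array 2 and 67 without vector array 1. S100P lost its call without LNCaP PURα array 1 (2.18) or 2 (1.70), and HERPUD1 without these (1.07 and 0.88) or without either PC3 array (0.81).

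The fixed lists that passed over both lines with the preset correlation were led by stress genes. The ATF4 and CHOP list had a median of 0.23 over 30 members, 26 above 0 (adjusted p = 9.2e-10, and adjusted p = 0.820 with an estimated correlation), and ATF4, DDIT4 and NUPR1 rose when adjusted over the list alone. Hypoxia and glycolysis had 0.19 over 28 members (adjusted p = 4.6e-06, and adjusted p = 0.820 with an estimated correlation), with DDIT4 and the collagen prolyl hydroxylase P4HA2 (0.83) rising over the list alone. The ER list had 0.17 over 29 (adjusted p = 1.7e-05, and adjusted p = 0.820 with an estimated correlation), with HERPUD1 rising over all genes and over the list alone. Cholesterol and fatty acid synthesis was lower (−0.14 over 23, adjusted p = 0.0045, and adjusted p = 0.820 with an estimated correlation), and SQLE (−0.59, but 0.11 on a dim probe set) and FASN (−0.64), which encode squalene epoxidase and fatty acid synthase, fell when adjusted over the list alone. Heat shock proteins (0.15 over 14) and androgen response (0.14 over 24) also passed (adjusted p = 0.0361 each, and adjusted p = 0.854 and 0.820 with an estimated correlation). With an estimated correlation none of the 6 passed (camera, 0 lists also at an unadjusted p under 0.05). Over the alternatives the lowest were 7.0e-16 (ATF4), 1.1e-10 (hypoxia), 1.0e-07 (ER), 0.0029 (cholesterol), 8.2e-05 (heat shock) and 0.022 (androgen). The other lists did not pass, and for 5 of them median and mean differed in sign. They were p53 targets (−0.0038 and 0.14, quantile median 0.0031), luminal (0.02 and −0.03), neuroendocrine (0.0018 and −0.048), interferon (−8.7e-05 and 0.012, quantile median 0.011) and NF-kB (0.09 and −0.02). Among the p53 targets, GADD45A, a growth arrest gene, and the kinase inhibitor CDKN2D (−0.08 on a dim probe set) rose when adjusted over the list alone. The ER list passed without each of the 6 arrays in turn, at 0.096 without LNCaP PURα array 2, and so did the ATF4 list, at 0.39 without LNCaP PURα array 1 and 0.11 without PURα array 2. Hypoxia lost its call without PC3 mock (0.075) or PC3 PURα (0.070) and read 0.33 without LNCaP vector array 1 and 0.30 without PURα array 1. Heat shock lost it without PC3 mock or PC3 PURα (0.030 each), LNCaP vector array 2 (0.080) or PURα array 1 (0.18) and read 0.28 without vector array 1. The androgen list lost it without vector array 2 (0.12), PURα array 1 (0.19) or PURα array 2 (0.10). The cholesterol list lost it without PURα array 1 (−0.068) and read −0.077 without either PC3 array and −0.28 without PURα array 2.

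**Figure D2:**
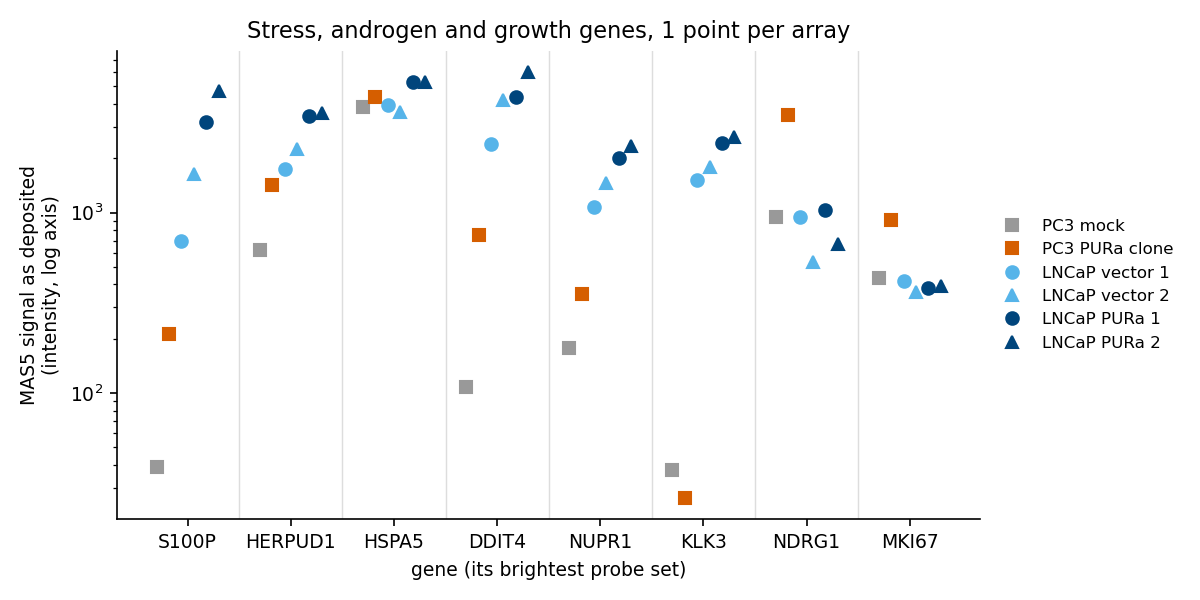
MAS5 signal on a log axis of 8 named genes, 1 point per array, squares for PC3, circles and triangles for LNCaP arrays 1 and 2. HERPUD1 reads 1428.4, 3431.3 and 3576.2 on the PURα arrays and 621.6, 1751.2 and 2240.5 on the controls of the same lines, and MKI67 is at 913.3 in PC3 PURα cells and between 364.9 and 435.2 on the other arrays.

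The PC3 arrays ask what differs in an androgen-independent line, which per the labels holds less PURα than LNCaP. With 1 clone against 1 mixed population, no test was possible between single arrays. The PURα clone had higher signal for UBE2QL1 (69.3 and 1144.8 in mock and PURα, 13.8-fold), the matrix protein TGFBI (9.6 and 302.9, 12.5-fold), and the aldehyde dehydrogenase ALDH2 (5.2 and 239.3, 12.1-fold). The secreted glycoprotein STC1 was higher as well (54.2 and 774.6, 11.4-fold), and so was IGFBP2, which binds insulin-like growth factors (35.1 and 485.3, 9.92-fold). They were followed by SLAMF9 (9.20-fold), the MAP kinase phosphatase DUSP1 (244.5 and 2205.9, 8.67-fold, but log2 −0.02 on another probe set) and the proteoglycan VCAN (139.8 and 1254.2, 8.28-fold), and then by ARSI (log2 2.95), the homeobox gene DLX3 (2.83), ADAMTS10 (2.79) and ESAM (2.74). It had lower signal for PHACTR3 (841.5 and 14.3, 27.8-fold lower), SSTR5-AS1 (405.6 and 13, 14.3-fold lower), the mucin MUC5B (200.9 and 4.6, 10.3-fold lower), EEF2KMT (339 and 22.7, 9.01-fold lower) and the sulfatase SULF2 (982.3 and 106.6). Also lower were the trefoil factors TFF2 (602 and 73.5, 6.78-fold lower) and TFF1 (1047 and 160.2, 5.92-fold lower), the transporter ABCC3 (6.60-fold lower), the receptor ROR1 (5.53-fold lower), GALNT14 (log2 −2.71), NAP1L3 (−2.60) and PKIB (−2.41). In all, 1378 of 27306 probe sets differed 2-fold or more, 805 higher and 573 lower. By comparison, 523 differed that much between the LNCaP vector arrays and 816 between the LNCaP PURα arrays. Among probe sets with a signal of 200 or more the numbers were 419 in PC3 against 16 and 60.

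By group, the PC3 clone was higher in hypoxia and glycolysis genes (median log2 0.60 over 29 members, 26 higher, above all 10000 random lists, whose central 95% ran from −0.17 to 0.15). Its members DDIT4 (108.5 and 756), ADM, which encodes adrenomedullin (294.1 and 1597.7), ANGPTL4 (11.2 and 107.7) and NDRG1 (951.1 and 3486.8) were among 6 that were 2-fold or more higher. Mitosis and G2/M genes were higher in 39 of 40 members (median 0.38, above all random lists), including RACGAP1 (1071.2 and 2659.3) and the proliferation marker MKI67 (435.2 and 913.3). By contrast, DNA replication and G1/S genes had a median of −0.13, with 15 of 38 higher. Mesenchymal markers had 0.37 over 19 members (percentile 99.9), led by TGFBI, COL1A1 (849.9 and 2572.2) and ZEB1 (191.6 and 432.3), with SPARC at −0.98. Notch, BMP, TGF-beta and Wnt targets had 0.26 over 23 (percentile 99.3), with ID1 at 2630.3 and 6745.4. The ATF4 and CHOP list stood at 0.29 over 30 (percentile 99.9; 24 higher, ATF3 107.1 and 266.7). The ER list stood at 0.20 over 28 (percentile 99.6; 21 higher, DNAJB9 164.9 and 340.1, XBP1 log2 0.66). Cholesterol and fatty acid synthesis was lower at −0.27 (percentile 0.070), with SREBF1 at 327.5 and 126 (log2 0.61 on another probe set), SCD at 1081.3 and 447.2 and FASN at 1553.2 and 683.4. Luminal markers were at −0.28 (percentile 1.08), with the prostate homeobox gene HOXB13 at 870.9 and 268.4, CDH1 (E-cadherin) at 68.4 and 4.3 (3.2 and 7.5 on its other probe set). CLDN7 went the other way at 18.7 and 94.8. The kinase inhibitors CDKN2D (84.2 and 586.1, but log2 −0.08 on a dim probe set) and CDKN1A (90.4 and 461.3) were higher, while the p53 list as a whole had a median of 0.09. These percentiles compare a list with other genes, not with other arrays. Under median scaling, arrays of the same LNCaP group differed by up to 0.61 on the ATF4 list, 0.33 on the ER list, 0.27 on the cholesterol list and 0.26 on the Notch list, close to PC3 or more, and by up to 0.25 on hypoxia, 0.24 on mitosis, 0.29 on mesenchymal and 0.22 on luminal genes, less than in PC3. With quantile normalisation they differed by up to 0.45 on the ATF4 list, still more than in PC3, but by 0.12, 0.03 and 0.07 on the ER, cholesterol and Notch lists, less than in PC3. Of the remaining lists, androgen response had 0.27, heat shock 0.16 (DNAJB1 1277.3 and 3646.4), basal markers 0.18, interferon 0.09, NF-kB −0.04 and ribosomal proteins −0.12. Neuroendocrine genes had 0.02, and a value just under 0 with the authors' scaling, with ENO2 at 635 and 1753.6 and NEFL at 4515.5 and 2054.8. Blood, endothelial and fibroblast markers had −0.11, which was 0.32 with a stricter filter on dim probe sets. That filter also moved the Notch list to 0.04, no filter moved the luminal list to −0.04, and the mean over all probe sets of a gene moved the androgen list to 0.02. Clone and PURα cannot be told apart in this comparison, since the only PURα sample is a clone and the mock cells are not.

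**Figure D3:**
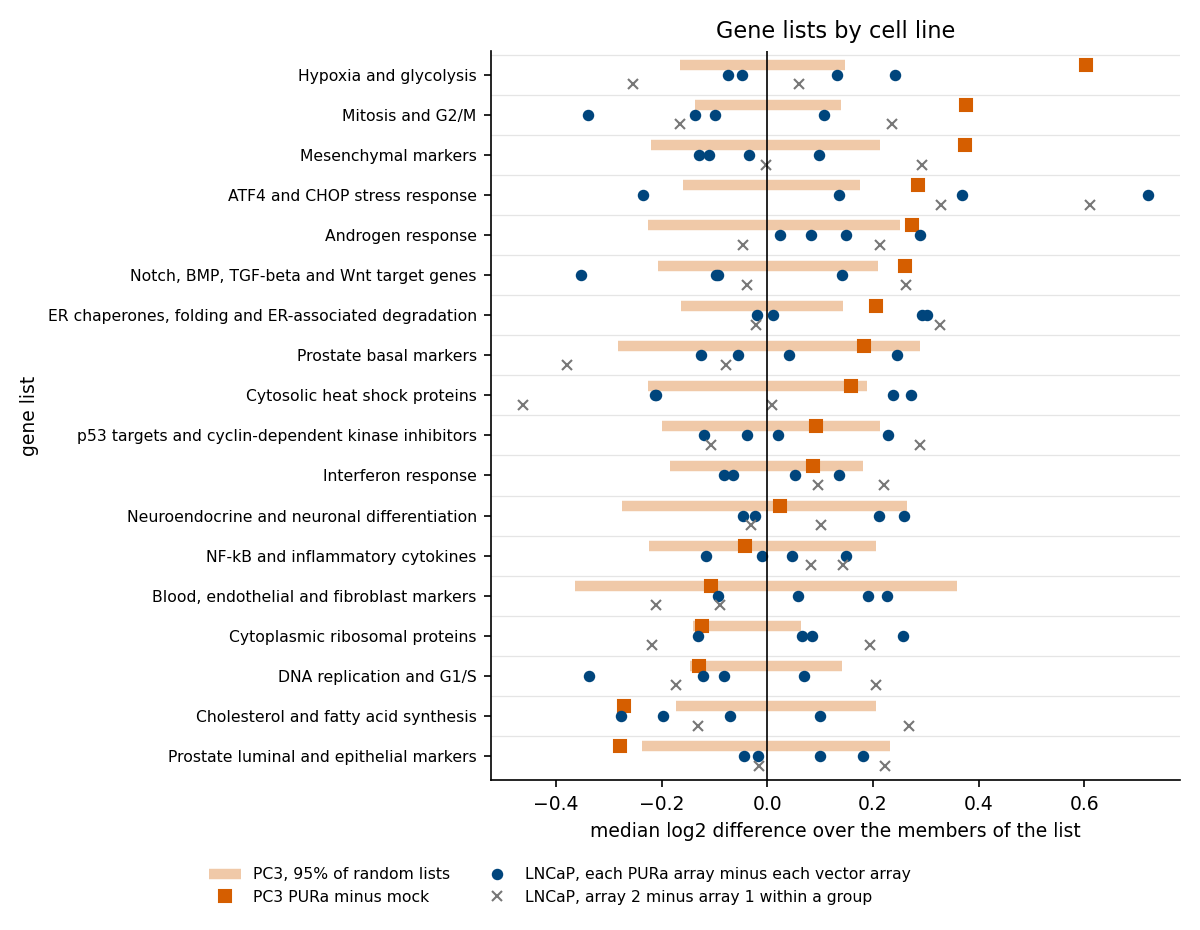
Median log2 difference over the members of each of the 18 fixed lists: squares for PC3 PURα minus mock over the central 95% of random lists; points for each LNCaP PURα array minus each vector array, and crosses for differences between arrays of the same LNCaP group. Hypoxia (0.60) and mitosis (0.38) lie outside the random range in PC3, and the LNCaP points of the ATF4 list run from −0.24 to 0.72.

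To ask how the lines compare, the difference between the PC3 clone and mock was tested against the PURα effect in LNCaP, taking the spread from the LNCaP arrays. PC3 arrays are assumed to vary like these, which 1 array per arm cannot show, and the difference need not come from PURα. The difference passed for STC1 (log2 4.0 higher in PC3 than in LNCaP), IGFBP2 (3.42), ALDH2 (3.39), VCAN (3.18) and DUSP1 (3.17, but −0.44 on another probe set). On the lower side it passed for EEF2KMT (−3.96), TFF1 (−3.33), GALNT14 (−2.99) and ROR1 (−2.67). All of these also passed with quantile normalisation and with the authors' scaling. In all, 241 probe sets passed, 133 higher and 108 lower. There were 56 under quantile normalisation and 47 with the authors' scaling, 40 of them shared with the 241 in each case. The count was 66 without LNCaP vector array 2, 67 without vector array 1 and 367 without PURα array 2. Among the lists, the mitosis genes differed most evenly, with all 40 members above 0 (median 0.51, adjusted p = 2.9e-08, and adjusted p = 0.959 with an estimated correlation) and none passing alone. The ER list did not pass (median −0.0024, quantile 0.016, camera adjusted p = 0.758).

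Across 12779 genes, the log2 difference in PC3 and the log2 change in LNCaP had a Pearson r of 0.113 and a Spearman rho of 0.144, and 0.270 and 0.254 over the 6574 genes brighter than a signal of 200. Genes are not independent replicates, so no p is given. The sign was the same for 55.3% of all genes and for 10 of the 16 genes that passed in LNCaP on their brightest probe set, PURA, S100P and H2AJ among them. The changes from the LNCaP infections, PURα 1 over vector 1 and PURα 2 over vector 2, had an r of 0.0093 over all genes and 0.255 over the brighter ones. Without the filter on dim probe sets the r between the lines was 0.054, and with a stricter filter 0.201.

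The lines themselves were compared to place PURα against their known difference in androgen dependence. Androgen response genes were higher in LNCaP, among them KLK3 (log2 −5.45, PC3 minus LNCaP, adjusted p = 8.0e-16), KLK2 (−5.27), TMPRSS2 (−4.94), STEAP2 (−4.15), KLK4 (−2.97) and FKBP5 (−2.01). Of 24 list members, 18 were higher in LNCaP and 4 in PC3. The largest differences named by the fixed rule were S100A6 (8.81), LGALS1 (8.59), IGFBP4 (8.19), the Wnt antagonist DKK1 (7.96), FABP5 (7.83) and FOSL1 (7.82) on the PC3 side. On the LNCaP side they were UGT2B28, an androgen-conjugating enzyme (−8.02), the epithelial factor EHF (−7.20), α-catenin (CTNNA1, −6.93, but 0.25 on another probe set), E-cadherin (CDH1, −6.58), MAGEA6 (−6.44) and RAP1A (−8.12, but 0.34 on another probe set). In LNCaP, S100A6, LGALS1, FABP5 and FOSL1 read between 2.3 and 25, around the pseudocount of 16, so the sizes of their differences depend on it. Basal markers were higher in PC3 for 7 of 8 genes and mesenchymal markers for 10 of 16. Luminal markers were higher in LNCaP for 15 of 20. In all, 12633 of 27306 probe sets differed, 5265 higher in PC3 and 7368 higher in LNCaP. PURA differed on probe sets B (−0.76, adjusted p = 0.0049) and A (−0.61, adjusted p = 0.011). It differed the other way on C (3.09, adjusted p = 0.0012), which was bright in the PC3 clone alone.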

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

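The tests of explanations in this part (array scaling, the variance prior, other splits of the arrays, differences within a group, signs shared with PC3) and the camera tests of the difference between the lines were chosen only after the results were seen. The test of that difference for single probe sets was planned.

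By the planned test, which assumes that PC3 arrays vary like LNCaP arrays, the difference between the PC3 clone and mock was unlike the PURα effect in LNCaP for 241 probe sets and, by camera, 5 lists. With 1 PC3 array per arm the assumption cannot be checked, and 419 bright probe sets differed 2-fold or more in PC3 against 16 and 60 within the LNCaP groups. The calls therefore do not show that PURα is what differs. As values of PC3 minus LNCaP on the log2 scale, the list medians were 0.51 for mitosis (adjusted p = 2.9e-08, and adjusted p = 0.959 with an estimated correlation) and 0.52 for hypoxia and glycolysis (7.2e-08, and adjusted p = 0.948 with an estimated correlation). They were 0.30 for Notch, BMP, TGF-beta and Wnt targets (0.0011, and adjusted p = 0.948 with an estimated correlation) and 0.42 for mesenchymal markers (0.0062, and adjusted p = 0.948 with an estimated correlation). The median was −0.50 for luminal markers (0.0037, and adjusted p = 0.959 with an estimated correlation). All 5 passed with quantile normalisation and with the authors' scaling. The mesenchymal list lost its call without LNCaP vector array 2 (0.23), and the Notch list read 0.19 without PURα array 1. Adjusted over the list alone, NDRG1, PFKFB3, P4HA2, DDIT4 and ADM differed in the hypoxia list and ID1, ID4 and LEF1 in the Notch list. So did COL1A1 and THBS1 in the mesenchymal list, CLDN7 (higher), CDH1 and HOXB13 (lower) in the luminal list, and no single member in the mitosis list.

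Of the named genes, 30 differed. Many genes were named for a large PC3 difference, which favours a call here, so this count does not show how common such differences are. The value was above 0 for PURA probe set C (6.62), STC1 (4.0), UBE2QL1 (3.75), IGFBP2 (3.42), ALDH2 (3.39), VCAN (3.18), DUSP1 (3.17), ADAMTS10 (3.07), ADM (2.57), CDKN2D (2.15), CDKN1A (2.05), DDIT4 (1.98), ICAM1 (1.93), SYT15 (1.88), NDRG1 (1.67), CLDN7 (1.67), ID1 (1.65), ENO2 (1.54), DNAJB1 (1.54) and COL1A1 (1.47). For ICAM1 and SYT15 the LNCaP change was below 0 (−1.72 and −0.98). Another probe set went the other way for ICAM1 (−0.76), DUSP1 (−0.44), CDH1 (0.52) and MYL10 (0.96). So did dim, untested ones, with log2 changes in PC3 and LNCaP of 0.12 and 0.45 for SYT15 and 0.27 and 0.58 for ADAMTS10. Probe set E of PURA had 0.08 and 0.29. The value was below 0 for ELK2AP (−1.66), CDH1 (−2.12), MYL10 (−2.50), PKIB (−2.51), TFF2 (−2.55), ROR1 (−2.67), GALNT14 (−2.99), SULF2 (−3.18), TFF1 (−3.33) and EEF2KMT (−3.96). Leaving out 1 LNCaP array moved some of these values. Without PURα array 1 the value was −3.79 for MYL10, 2.90 for SYT15 and 1.08 for ICAM1. Without PURα array 2 it was −1.21 for MYL10 and 0.85 for SYT15. With quantile normalisation 13 of the 30 passed, with the authors' scaling 12, and 12 with both: PURA, STC1, IGFBP2, ALDH2, VCAN, DUSP1, CLDN7, CDH1, ROR1, GALNT14, TFF1 and EEF2KMT. Of the 30, 15 passed without each LNCaP array in turn.

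For the mitosis and hypoxia lists, higher with PURα in PC3 than in LNCaP, the size hardly depended on array scaling. The smaller of the quantile medians was 0.47. Scaling moved the PC3 arrays by −0.03 and −0.004, so another scaling could hardly move these medians. The single PC3 clone or its culture, such as how dense or how well fed that dish was, may account for both lists, and PURα may act differently in the cell lines. With 1 PC3 PURα sample measured, these explanations cannot be told apart: clone, plasmid, medium and line all go together.

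For the 40 probe sets that passed in LNCaP, the size of the changes hardly depended on array scaling. Their median size under quantile normalisation was 99.2% of that reported (1.48 against 1.49), all 40 with the same sign. Median scaling moved the PURα arrays in opposite directions (−0.13 and 0.14), so it could hardly move the difference between the arms. The sizes are therefore no test of scaling as the source of the calls, which did depend on it. With quantile normalisation only 2 stayed past the threshold, both of PURA. There the prior degrees of freedom of the variance fell from infinite to 6.54. With these held infinite on the quantile values, 376 passed, all 40 among them. Array-to-array differences unrelated to PURα may account for the calls: setting vector 1 and PURα 1 against vector 2 and PURα 2 called 77 probe sets under median scaling, and the third split called 1. With quantile normalisation or the authors' scaling the split that gave 77 gave 0, where PURα gave 2. Its prior degrees of freedom fell from infinite to 6.13 and 7.25 there, much as for PURα. The 77 calls therefore do not by themselves show a structure of the samples. An effect of PURα shared with PC3 stays open. Of 15 genes other than PURA called on their brightest probe set, 9 had the same sign in PC3, against 55.3% of all genes. The exact binomial test (one-sided p = 0.462) treats genes as independent replicates, which they are not, so it cannot decide this.

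For the stress lists in LNCaP, the list medians hardly depended on array scaling. The quantile medians were 0.233 for ATF4 and 0.168 for the ER list. Scaling moved the arrays of an arm in opposite directions (0.06 and −0.03 for vector, −0.13 and 0.14 for PURα). Another scaling could therefore hardly move these medians, which do not test scaling as the cause. Array-to-array differences unrelated to PURα may account for the ATF4 shift. Arrays of the same group differed by up to 0.61 on it, more than the shift of 0.23. The split by replicate number gave a median of −0.47, as array 2 read higher than array 1 in both arms (0.33 and 0.61). Between arrays of the same number PURα minus vector was 0.13 and 0.37, and 0.35 and 0.17 with quantile normalisation. The crossed comparisons gave −0.24 and 0.72, and −0.15 and 0.65 with quantile normalisation. If the numbers pair, both pairs lie above 0, but whether they pair is open. For the ER list the largest difference within a group was 0.33 under median scaling and 0.12 under quantile normalisation, where the comparisons of PURα with vector arrays ran from 0.10 to 0.21. With the authors' scaling the differences within a group were 0.07 and 0.06, below all comparisons of PURα with vector arrays (from 0.11 to 0.22). Under quantile normalisation the 0.12 lay within the range of the comparisons, and under median scaling the 0.33 lay above all of them. That 0.33 was between the PURα arrays, which median scaling moved by −0.13 and 0.14. Between the same 2 arrays the list differed by 0.06 with the authors' scaling and 0.03 with quantile normalisation, so the 0.33 largely reflects the scaling. The 0.12 was between the vector arrays and is not removed this way. With 2 arrays per arm, array differences and PURα therefore cannot be told apart for this list. The other splits of the 4 LNCaP arrays called 3 lists each against 6 for PURα, and 5 and 0 against 6 with quantile normalisation.

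Over both lines, PURα against control called 12 probe sets, 1 of the 10 splits of the 6 arrays gave as many, and the highest other split gave 0; with 10 splits the share cannot be under 0.05. For the fixed lists, PURα called 6, 4 of the 10 splits gave as many, and the highest other split also gave 6; again the splits are too few for a share under 0.05. With quantile normalisation PURα called 7 and the highest other split 5.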

How the results depend on the processing

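The authors' scaling and the checks of the variance prior were added after the data were seen; the others were planned. Outside the counts, 2707 of 3047 gene tests and 808 of 900 list tests kept direction and side of the threshold (253 and 62 weaker, 87 and 25 stronger, 5 list tests reversed). Most of these tests had not passed in the main fits, and staying below the threshold counts as kept. The shares therefore do not measure how stable the calls are. Without the filter 53 of 212 gene tests were weaker, and with quantile normalisation 38 of 212. Of PC3 values, 861 of 910 for genes and 212 of 216 for lists stayed within the spread between arrays (0.353 and 0.160 on the log2 scale). Of the count comparisons, 135 of 267 stayed within 1.5 times. The called LNCaP probe sets are mostly dim, and their calls rest on how the variance is modelled.

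Without the filter, LNCaP gave 0 probe sets (limma; 2310 at an unadjusted p under 0.05), both lines 0 (2811 at an unadjusted p under 0.05), the difference between lines 1, PC3 4119 at 2-fold, LNCaP lists 3 and r 0.054. PURA kept 1.77 with an adjusted p = 0.515. The number of tests is not why: adjusted over the filtered probe sets this LNCaP fit still gave 0 (PURA 0.258), and with the prior degrees of freedom (6.87) held infinite 31. With the 70th percentile the numbers were 6, 93, 101 and 636, r 0.201, and the PC3 blood, endothelial and fibroblast median turned from −0.11 to 0.32. Quantile normalisation gave 2, 1 and 56, and the authors' scaling 2, 1 and 47, with prior degrees of freedom down from infinite to 6.54 and 7.02 in LNCaP. A pseudocount of 1 gave 5 over both lines, 443 for the difference, 2111 in PC3 and 3 LNCaP lists, and a pseudocount of 64 gave 523 in PC3. With no intensity trend LNCaP gave 117, both lines 2 and LNCaP lists 2, and robust moderation gave 27 over both lines. For the 70th percentile, the pseudocounts, the trend and robust moderation the cause was not tested. The replicate block gave 105 over both lines (all 12 among them), 131 for the difference and 2 LNCaP lists. The residuals of arrays with the same number correlated at 0.038 between the arms. The split by replicate number called 77 probe sets under median scaling, where its prior degrees of freedom were infinite. It called 0 with quantile normalisation or the authors' scaling, where they were 6.13 and 7.25. The 77 calls therefore do not show that the numbers pair, and whether they pair stays open. The cause was not tested for the block, nor for 1 probe set per gene. With 1 probe set per gene, LNCaP gave 15, the difference 130, the lines 6497 and PC3 633. A threshold of 0.1 gave 61 in LNCaP and 20 over both lines. The Gamma-Gamma model gave 108 in LNCaP (54 each way, 35 shared with limma). With an estimated correlation camera called 0 lists in LNCaP and 0 over both lines (0 at an unadjusted p under 0.05 in each). The ER and ATF4 medians stayed 0.15 and 0.23 in LNCaP (adjusted p = 0.853) and 0.17 and 0.23 over both (adjusted p = 0.820).

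Leaving out 1 array, where a lone sample left in an arm is assumed to vary like the others, gave 15 to 185 probe sets in LNCaP, 0 to 67 over both lines, 66 to 367 for the difference and 2 to 5 LNCaP lists. The LNCaP ATF4 median ran from −0.027 (without PURα 2) to 0.54, the LNCaP mitosis median from −0.22 to 0.0072 (without PURα 1), the mitosis median over both lines from −0.11 (without either PC3 array) to 0.17, and the p53 median over both lines from −0.037 to 0.082.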

Other observations

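The camera tests between the lines in this part were chosen only after the data were seen. PC3 and LNCaP differed in more groups of genes than those of the prostate lineage. The ATF4 and CHOP list was higher in LNCaP for 23 of 30 members (median PC3 minus LNCaP −1.34, camera adjusted p = 2.3e-07, and adjusted p = 0.570 with an estimated correlation). The same held for cholesterol and fatty acid synthesis in 14 of 23 (−0.88, adjusted p = 6.6e-04, and adjusted p = 0.570 with an estimated correlation). It also held for ribosomal proteins in 30 of 40 (−0.64, adjusted p = 4.4e-05, and adjusted p = 0.639 with an estimated correlation). The ribosomal median was −0.38 with quantile normalisation. NF-kB and cytokine genes were higher in PC3 for 11 of 18 (0.85, adjusted p = 2.3e-05, and adjusted p = 0.150 with an estimated correlation). Interferon genes were higher in PC3 for 15 of 29 (0.84, adjusted p = 7.3e-04, and adjusted p = 0.376 with an estimated correlation). Smaller differences toward PC3 passed for mitosis (0.27), DNA replication (0.22) and hypoxia (0.47), with adjusted p = 0.684, 0.639 and 0.639 with an estimated correlation. With an estimated correlation no list passed between the lines (camera, 0 of 18, with 3 at an unadjusted p under 0.05). That includes androgen response (−2.86, adjusted p = 0.150), basal (2.71, adjusted p = 0.150), mesenchymal (2.31, adjusted p = 0.264) and luminal markers (−1.57, adjusted p = 0.264). The ER list did not pass as a list (−0.15), though 6 of its 29 members were higher in PC3 and 9 in LNCaP. Heat shock (0.27, camera adjusted p = 0.102) did not pass either, but did with quantile normalisation. Nor did p53 targets (−0.38), neuroendocrine (0.17) and blood, endothelial and fibroblast markers (0.18). Of the p53 targets 5 were higher in PC3 and 11 in LNCaP, and of the neuroendocrine genes 6 and 3. The Notch, BMP, TGF-beta and Wnt list had a median of −0.15, a mean of 0.37 and a test pointing up.

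Some stress genes started at different levels. DDIT4 read 108.5 in PC3 mock and 2401.7 and 4195.8 on the LNCaP vector arrays, NUPR1 178.2 against 1077.8 and 1458, and HERPUD1 621.6 against 1751.2 and 2240.5. In PC3 PURα cells they read 756, 355.1 and 1428.4.

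The PURA probe sets differed in their signal in the PURα cells. On probe set C the PC3 PURα clone read 19090.2 and the LNCaP PURα arrays 227 and 193.2, while on probe set B they read 1881, 2094.7 and 2509.3. The positions of the probe sets on the transcript and the extent of PURA sequence in the constructs were not analysed here.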
